A study of Homo sapiens with 4 samples.

How the data were processed

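Total RNA from Huh7 cells was amplified, labelled with biotin and hybridized to Illumina bead arrays, per the labels' protocols. The 4 samples formed 2 groups by the telomere length in their labels, short and long, with 2 arrays each. The titles carry a replicate number, but the labels do not say that a number marks a shared day or culture, so the main comparison treated the arrays as unpaired.

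The signal table held 47320 probes for each array on a log2 scale, as deposited by the authors. The base of the logarithm is not named in the file and was taken as 2 from the range of the values. GenomeStudio 2011.1 and R 2.15.1 were used by the authors, per the submitters' processing notes. The sorted signals of the 4 arrays were the same to within 0.0003 of their mean, so the authors' deposited log2 values were read as quantile normalized and were not normalized again. No detection p-value was given, so no detection filter was applied, and the signal over background of single probes is unknown. For arrays, their number limits the precision. No pair of arrays shared more than 25 identical values, so no array was a copy of another.

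The second table was the output of a DAVID functional annotation clustering, per the file headers. For each term it gives the count of listed genes, their percent of the input list, a p-value (the modified Fisher test called EASE), the fold enrichment, and Bonferroni, Benjamini and FDR values, all as deposited by the authors. Terms printed more than once were merged, which left 622 of 642 lines. The p-value of all 622 terms was recomputed from the deposited counts and lay within 0.05 of the deposited one on the log10 scale. The rule by which the authors chose the genes is not stated, and the table gives no direction.

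Differences between groups were tested on every probe with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a constant prior, two-sided, contrast short minus long telomere), with Benjamini-Hochberg adjustment over 47320 probes and a threshold of 0.05. A test per gene had been planned before the data were examined, along with camera and fry tests of gene lists. These were not run because the files used here do not pair probes with genes. A rule of size was given beside the test: an at least 2-fold difference of group means with groups that do not overlap. A 1.5-fold and a 1.3-fold level were added after the data were seen. The naming rule, fixed before the data were examined, took the 12 largest differences past the test in each direction whose groups did not overlap, filled where fewer passed with probes at an unadjusted p under 0.01, and added members of the gene lists. As probes could not be named, at most 2 identifiers per direction were printed under it, with values only for any further probe.

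The tests were checked on simulated data before use. For the comparison of short with long telomeres, 200 of 47320 simulated probes were given a 1.5-fold, 2-fold or 3-fold change. With variances drawn from the fitted prior, limma recovered 23.9% of the 1.5-fold, 95.5% of the 2-fold and 98.5% of the 3-fold changes, and 4.6% of its calls were false. With each probe's fitted variance after shrinkage toward the prior, it recovered 77.6% of the 1.5-fold and 100% of the larger changes. Of its calls there, 13.1% were false. The simulated arrays shared no difference between the replicate numbers, so recovery on the real arrays may differ.

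Gene symbols in the authors' table were matched to RefSeq gene names of assembly GRCh38.p14. Of 198 symbols, 189 matched a protein-coding gene. The overlap of these genes with 40 gene lists, 963 genes fixed before the data were examined, was tested with a two-sided Fisher's exact test against 20056 protein-coding genes, with Benjamini-Hochberg adjustment over the 40 lists. This overlap test, and the naming of the listed members of lists and terms, were chosen after the table was seen. The genes that the array measures and the cells express were not known, so part of an overlap could come from the choice of background, and the union of the fixed lists was used as a second background. Near-identical families (the 6 listed metallothioneins, ORM1 with ORM2, FAM21A with FAM21C) were also counted once. Metallothioneins that the authors did not list were not merged, which left 5 of the 10 genes of that fixed list. For the authors' terms, the Benjamini value was then recomputed over the number of tests implied by the deposited Bonferroni values, 1562 for biological processes and 334 for keywords, and is an upper bound because only the deposited terms could be ranked. In 200 random draws of genes, the list test called any list in 1. The draws were uniform over all protein-coding genes, so they do not show how often lists are called for annotated, measured or expressed genes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

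Alternatives fixed before the data were examined were centring of each array on its median, the probes above the median signal alone, a trended and robust prior, the replicate number as a block, a 2-fold threshold beside the adjusted p, and leaving out each array in turn. Leaving out one array leaves a group with 1 array, which limma assumes to vary like the other group.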

Results

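Gene expression was measured in Huh7, a human hepatocellular carcinoma cell line, in cells labelled as having short telomeres and in cells labelled as having long telomeres, with 2 Illumina bead arrays for each state. The labels gave the same hydrogen peroxide note, 300 uM for 4 days, for all 4 samples, so the labels do not separate the groups by exposure. They did not say whether exposure differed in practice, how telomere length was set, or whether the arrays of a group came from separate cultures. The limma p-values below therefore measure only the spread between these samples. The enrichment and list p-values are computed from counts of genes and measure no spread between samples. Each array held a normalized signal for 47320 probes, with a median of 7.17 and a range of 6.05 to 15.83 on a log scale taken as base 2. Across probes, which are not independent replicates, Pearson's r was 0.993 between the short telomere arrays, 0.994 between the long telomere arrays, and 0.990 to 0.995 between arrays of different groups. A second deposited table held the authors' enrichment analysis, which named genes without a direction or an expression value. The files used here do not pair probes with genes, so a probe is given by its identifier alone and a gene named by the authors is given no direction. The 2 arrays per group limit the precision of every difference.

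The first comparison asked which transcripts differed in level between Huh7 cells with short and with long telomeres. Past an adjusted p of 0.05 in limma, 6 probes were lower and 1 was higher in the short telomere cells, too few for a general direction, with differences of 0.99 to 1.43 on the log2 scale and mean signals between 8.04 and 10.53. Of the probes past the test, ILMN_3251662 differed most, with 9.81 ± 0.13 in short telomere cells and 11.24 ± 0.12 in long telomere cells (log2 signal, mean ± SD, n = 2 each). Its log2 difference was -1.43 with a standard error of 0.116, a 2.70-fold lower signal with short telomeres (limma, adjusted p = 0.0224). ILMN_3239574 had 9.39 ± 0.05 against 10.68 ± 0.16, a log2 difference of -1.29 with a standard error of 0.115 and a 2.45-fold lower signal (limma, adjusted p = 0.0224). In the other direction, ILMN_1808494 had signals of 10.93 and 11.07 on the short telomere arrays (SD 0.10) and of 10.05 and 9.95 on the long telomere arrays (SD 0.07), a log2 difference of 0.999 with a standard error of 0.108, just under 2-fold (limma, adjusted p = 0.0489). The next highest, ILMN_1730625, stood at 11.3 ± 0.14 against 10.31 ± 0.14 and did not pass (log2 difference 0.99, standard error 0.119, limma adjusted p = 0.0882).

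**Figure D1:**
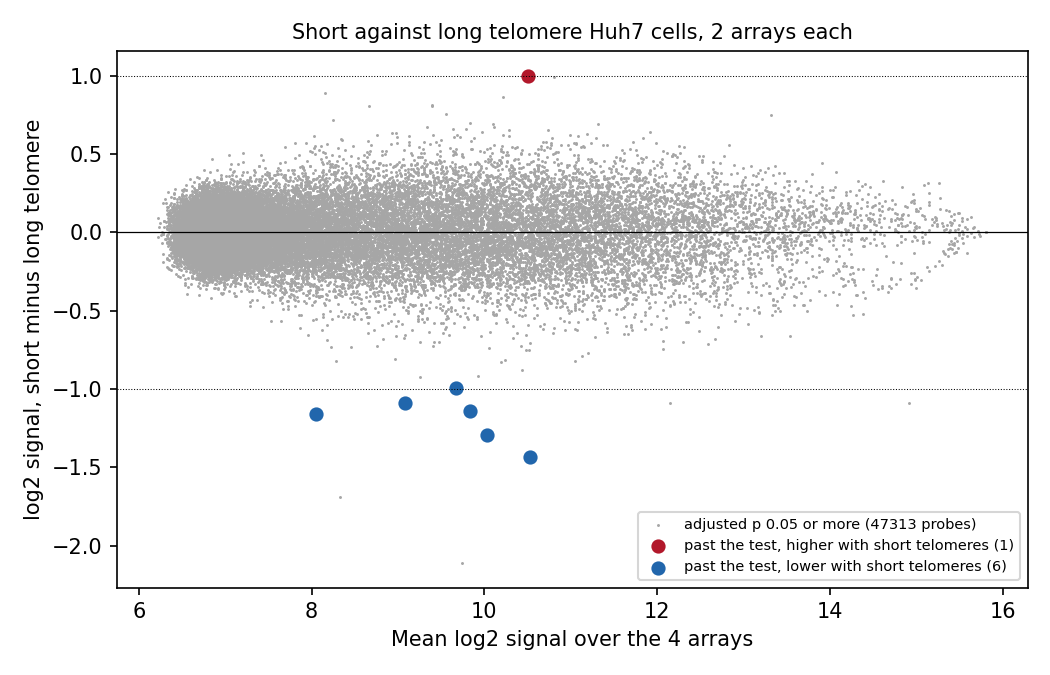
Log2 difference (short minus long telomere, vertical axis) against the mean log2 signal over the 4 arrays (horizontal axis) for 47320 probes; dotted lines mark 2-fold. The 1 probe past the test and higher with short telomeres is red, the 6 lower ones are blue, and the largest negative differences of all, at -2.11 and -1.69, are grey because they did not pass.

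By size alone, the differences were small and leaned toward lower signal with short telomeres. At least 2-fold, 9 probes were lower and 0 were higher in short telomere cells, and in 8 of the 9 the groups did not overlap. Chance gives non-overlap in 33.3% of unselected probes with 2 arrays against 2. Probes picked for a large difference of means overlap less often, so this share is no baseline for the 9. The 2 largest of these 8 did not pass the test, at 4.32-fold (short telomere SD 0.80, limma adjusted p = 0.17) and 3.23-fold (short telomere SD 0.82, limma adjusted p = 0.179). Another probe of the 8 had 14.38 against 15.46, near the highest signal of the arrays, and did not pass either (limma, adjusted p = 0.169). At least 1.5-fold without overlap, 83 probes were lower and 42 were higher. At least 1.3-fold without overlap, the directions were nearly even, with 562 lower and 558 higher. An unadjusted p under 0.05 in limma was found for 3889 probes, of which 1965 were higher and 1924 lower, where 2366 would be expected by chance. An exact permutation test of a single probe cannot go below p = 0.333 in this design.

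The number of probes past the test changed with the probes, prior and arrays used. A block on the replicate number, whose meaning is not labelled, moved it most and is given with the processing choices below. Limma called 0 of the 23660 probes with the higher mean signal when these were tested alone (lowest adjusted p 0.15, with 3086 at an unadjusted p under 0.05), and 16 higher and 38 lower probes with a prior variance that follows the signal. It called 0 probes without long telomere replicate 1 (2961 at an unadjusted p under 0.05), 0 higher and 2 lower without long telomere replicate 2, and 3 higher and 10 lower without short telomere replicate 2. The counts by size rose when any one array was left out, to between 14 and 28 probes for 2-fold and between 207 and 600 for 1.5-fold. A group is then 1 array with a noisier mean, and chance gives non-overlap in 66.7% of unselected probes.

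The second comparison asked which gene groups stood out among the genes the authors took to differ between the states. Metal-binding metallothioneins came first, followed by proteins that the liver secretes into plasma and by ribonucleoproteins. The authors' deposited table had 89 annotation clusters and 622 distinct terms, drawn from an input of 229 genes of which 198 are named. The terms of the authors' deposited table past a Benjamini value of 0.05 numbered 17, and 14 of them held metallothioneins, small cysteine-rich proteins that bind zinc, copper and cadmium. The 6 metallothioneins were MT1A, MT1F, MT1G, MT1H, MT1X and MT2A. They made up 6 of the 8 genes with the keyword chelation, a 67.7-fold enrichment (authors' deposited table, EASE modified Fisher exact p = 8.46e-09). In 12 of these 14 terms past the threshold they were the only listed genes. The other 2 of these 14 terms in the authors' deposited table were metal binding, which added TF (7 genes, p = 4.02e-08), and acetylated amino end, which added 6 genes including ACTG1, LDHB and HSPE1 (12 genes, p = 1.35e-08). Metallothionein transcripts are near-identical, so a probe for one may also bind others, and the 6 names are uncertain as separate signals. With each near-identical family counted once, 0 of the 17 terms kept a recomputed Benjamini value under 0.05, metallothioneins then counting as 1 gene. For the 12 terms with metallothioneins alone this was fixed in advance, since a term left with 1 gene cannot pass. It is therefore no check of those terms.

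The 3 remaining terms concerned plasma proteins and ribonucleoproteins, and with families counted once their recomputed Benjamini values were 0.163 for acute-phase response, 0.391 for plasma and 0.19 for ribonucleoprotein. These are upper bounds, and ribonucleoprotein kept its 11 genes and moved because the metallothionein terms no longer ranked ahead of it. The authors' deposited table gave 7 genes for acute-phase response, a 14.3-fold enrichment with a Benjamini value of 0.0127. They were the orosomucoids ORM1 and ORM2, which share most of their sequence and are uncertain as separate signals, the iron carrier transferrin (TF), the protease inhibitors SERPINA1 and SERPINA3, fetuin A (AHSG), and STAT3, the transcription factor that carries interleukin-6 signals to acute-phase genes. The keyword plasma held 7 genes, with apolipoprotein C3 (APOC3) in place of STAT3, at a 6.80-fold enrichment and a Benjamini value of 0.027 in the authors' deposited table. The keyword ribonucleoprotein held 11 genes at a 3.56-fold enrichment and a Benjamini value of 0.0448 in the authors' deposited table. Among these were the ribosomal proteins RPL14, RPL26, RPL36A, RPLP0 and RPS24, the mitochondrial ribosomal protein MRPL48, the splicing-related LSM2 and HNRNPU, and NHP2, a component of box H/ACA particles including telomerase.

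Of 40 gene lists fixed before the data were examined, 6 held more of the authors' genes than expected from all protein-coding genes (two-sided Fisher's exact test, Benjamini-Hochberg over the 40 lists). Metallothioneins had 6 of 10 genes listed where 0.0942 were expected, an odds ratio of 162 with a 95% interval of 38.1 to 789 (adjusted p = 5.27e-09). Hepatocyte secreted proteins had 7 of 45 genes listed, AHSG, APOC3, ITIH2, ORM1, SERPINA1, SERPINA3 and TF, where 0.424 were expected (odds ratio 20.1, 95% interval 7.46 to 46.3, adjusted p = 3.96e-06). TGF-beta response genes had 3 of 20 listed, the matricellular CYR61 and the transcription factors KLF10 and TGIF1 (odds ratio 18.8, 95% interval 3.50 to 65.9, adjusted p = 0.00834). DNA replication genes and E2F targets had 4 of 40 listed: the primase PRIM1, the helicase subunits MCM4 and GINS2, and the dUTPase DUT (odds ratio 11.9, 95% interval 3.05 to 33.7, adjusted p = 0.00714). Mitosis genes had 3 of 36 listed, the spindle motor KIF11 with DLGAP5 and HMMR (odds ratio 9.69, 95% interval 1.89 to 31.3, adjusted p = 0.0312). Cytosolic ribosomal proteins had 4 of 61 listed, RPL14, RPL26, RPLP0 and RPS24 (odds ratio 7.51, 95% interval 1.96 to 20.6, adjusted p = 0.021). The authors chose these genes on the same samples, so the overlaps are not independent evidence, and none carries a direction. The genes tested were those named in the authors' annotation clusters, 189 matched of an input of 229, which favours annotated genes and with them curated lists. In the authors' deposited table, which has its own background, related terms for 3 of these lists did not pass the Benjamini threshold. DNA replication held the 4 replication genes among 5, at 2.14-fold (Benjamini value 0.896). Cytosolic ribosome held the same 4 ribosomal genes at 4.18-fold (Benjamini value 0.69). Mitosis held 4 genes, with KIF11 and DLGAP5 but not HMMR, at 1.48-fold (Benjamini value 0.987). The broader keyword ribonucleoprotein, which includes the 4 ribosomal genes, did pass. Against the genes of the fixed lists alone, which are better annotated than most genes, only metallothioneins remained past the test (adjusted p = 0.000104), and hepatocyte secreted proteins had an adjusted p of 0.131. With each near-identical family counted once, metallothioneins had 1 of 5 genes listed (same exact test, adjusted p = 0.179). Only the metallothioneins that the authors listed were merged, so the fall in their count was built in and is no independent check. The other 5 lists kept their counts because they hold no collapsed genes.

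**Figure D2:**
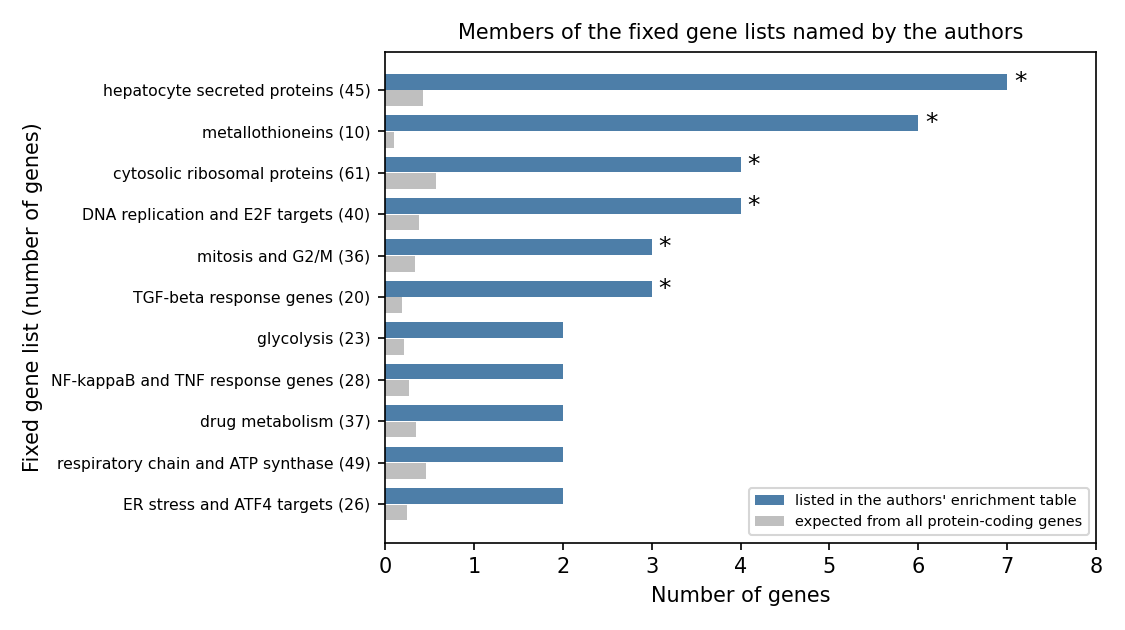
Number of genes of each fixed list named by the authors (blue bars) beside the number expected from all protein-coding genes (grey bars), for the lists with at least 2 named members; the list size stands in parentheses. An asterisk marks the 6 lists with an adjusted p under 0.05, from 7 of 45 hepatocyte secreted proteins and 6 of 10 metallothioneins down to 3 of 20 TGF-beta response genes.

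No list of telomere maintenance, damage response or stress genes other than metallothioneins passed the test. Several had more members than expected, but below 1 gene was expected of each list, so 1 listed gene already exceeded it. Shelterin, CST and telomerase components had 1 of 24 genes listed, NHP2, where 0.226 were expected (odds ratio 4.59, 95% interval 0.111 to 28.6, Fisher's exact test, adjusted p = 0.388). Genes reported to lie under telomere position effects had 0 of 6 and DNA damage signalling and repair had 0 of 31, where 0.0565 and 0.292 were expected, with upper bounds on the odds ratio of 89.8 and 13.4. The p53 target list had 1 of 26, the cell cycle arrest gene GADD45A, and senescence-associated secreted factors had 1 of 30, the chemokine CXCL2. Of the stress lists, NRF2 targets had 1 of 26, the ferritin chain FTH1, heat shock proteins had 1 of 18, HSPE1, and peroxide and superoxide removing enzymes had 0 of 27. Intervals this wide leave sizeable over-representation of these lists open.

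Several metabolic and signalling lists had a small number of members and did not pass after adjustment. The unadjusted Fisher's exact p was under 0.05 for glycolysis with 2 of 23 (LDHB and TPI1, adjusted p = 0.112), endoplasmic reticulum stress and ATF4 targets with 2 of 26 (SLC3A2 and VLDLR, adjusted p = 0.124), NF-kappaB and TNF response genes with 2 of 28 (CXCL2 and KLF6, adjusted p = 0.126), and drug metabolism with 2 of 37 (CYP2C8 and SULT2A1, adjusted p = 0.19). The respiratory chain and ATP synthase had 2 of 49 (ATP5I and SDHC, adjusted p = 0.283). In the fixed lists, 1 gene each was listed for fatty acid synthesis (FADS1), fatty acid oxidation (VNN1), bile acids (AMACR), hypoxia (ADM), YAP targets (CYR61), apoptosis regulators (TNFRSF10A), the histones of the fixed list (HIST2H2BE), epithelial junctions (JUP), and liver progenitor markers (ANPEP). No member was listed of the fixed lists for mitochondrial biogenesis and sirtuins, autophagy, interferon-stimulated genes, epithelial-mesenchymal transition, hepatocyte transcription factors, cholesterol synthesis, gluconeogenesis with urea cycle, or Wnt targets. The authors also named the sirtuin SIRT7 and the histone HIST1H4E, which are not members of these fixed lists. Among markers of other cell types, leukocytes had 1 of 16, LYZ, and fibroblasts, endothelium and biliary epithelium had 0.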

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

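The 1.5-fold count, the alternatives for the gene lists and those for the authors' terms were chosen only after the results were seen. Against 1 higher and 6 lower probes in limma, centring the arrays on their medians gave 1 and 6. All 4 arrays had the same median of 7.17, so the counts with centring were fixed in advance and are no check. Asking for a 2-fold difference as well gave 0 higher and 5 lower, since the 1 higher probe lay just under 2-fold. The brighter 23660 probes tested alone gave 0 higher and 0 lower, with 3086 at an unadjusted p under 0.05: the log2 differences were unchanged and the prior degrees of freedom fell from 6.9 to 4.3, but the cause was not tested. A trended and robust prior gave 16 higher and 38 lower, which included all 7 probes of the main test; the cause was not tested further. Leaving out one array gave 0 to 3 higher and 0 to 10 lower probes: 0 and 0 without long telomere replicate 1 (2961 at an unadjusted p under 0.05), 0 and 2 without long telomere replicate 2, 3 and 10 without short telomere replicate 2, and 1 and 8 without short telomere replicate 1, with 0, 1, 5 and 7 of the 7 probes shared. The 2-fold count without overlap was 8 with centring and among the brighter probes, and 14 to 28 with one array left out; the 1.5-fold count was 125 and then 207 to 600. Without asking for non-overlap these were 14 to 28 and 210 to 601, so more probes passed the fold limit itself, as a group of 1 array has a noisier mean. With the replicate block, limma called 919 higher and 959 lower probes, including all 7, and 1706 of these 1878 had an unadjusted p under 0.05 without it. The check of the numbers, over the probes above the median signal, gave a correlation of 0.632 between the replicate difference of the short and that of the long telomere arrays, but with 2 pairs and no label on the numbers' meaning they do not establish a pairing. The log2 differences of the 4 identified probes kept their sign in every alternative run, which was fixed in advance and is no check. These probes were chosen with groups that do not overlap, so leaving out 1 array cannot turn the sign. The other alternatives left the differences unchanged. The calls of the 4 probes turned in some runs. Among the brighter probes, ILMN_3251662, ILMN_3239574 and ILMN_1808494 no longer passed (limma, adjusted p = 0.15, 0.165 and 0.195). ILMN_1730625, which had not passed, did so with the trended and robust prior (limma, adjusted p = 0.0103) and with the replicate block. Fixed lists past the test numbered 6, and 1 with the union of the lists as background. Counting near-identical families once gave 5, but it could move metallothioneins alone and merged only those that the authors listed. Terms past the threshold in the authors' deposited table numbered 17 by Benjamini, 15 by Bonferroni and 36 by an FDR under 5 percent, a looser threshold. A recomputed Benjamini value with near-identical families counted once, an upper bound for each value, gave 0. For the 12 terms with metallothioneins alone this was fixed in advance, as 1 gene was left in each. The mean of a gene's probes, the camera and fry tests, and the direction of the authors' genes were not run because the files used here do not pair probes with genes. Without detection p-values, how far dim probes lay above background is unknown.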

Other observations

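Except for the chromosome-end test, all tests below were chosen only after the results were seen. Beyond the terms past the Benjamini threshold, the authors' deposited table named further gene groups that did not pass it. In the authors' deposited table, inflammatory response had 13 genes at a 3.26-fold enrichment with a Benjamini value of 0.283, and response to drug had 10 genes at 3.77-fold with a value of 0.341. Regulation of apoptosis had 19 genes (authors' deposited table, 1.93-fold, Benjamini value 0.534), among them the death receptor TNFRSF10A and its ligand TNFSF10, the redox regulator TXNIP, the transcription factor FOXO3, the prostaglandin synthase PTGS2, and ERN1, a sensor of unfolded proteins. Amino acid transmembrane transporters numbered 5, SLC1A3, SLC3A2, SLC6A14, SLC38A1 and SLC43A1 (authors' deposited table, 6.67-fold, Benjamini value 0.565), and steroid metabolic process had 8 genes (3.23-fold, Benjamini value 0.558). Cell cycle had 16 genes at 1.68-fold with an unadjusted p of 0.052, and DNA replication had 5 at 2.14-fold with 0.202, both in the authors' deposited table.

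Few probes passed limma although many had small shifts. A difference between the arrays numbered 1 and those numbered 2 that both telomere states share is a candidate explanation, since it would add to the spread within each group. The replicate differences of the short and of the long telomere arrays correlated at 0.632 across the probes above the median signal, which a shared difference needs. Split by number, the 4 arrays had 420 probes at least 1.5-fold apart without overlap, against 125 for the telomere groups and 0 for the crossed split. So 2 of the 3 splits reached the real value, and the split by number points to a structure of the arrays other than telomere length. Across the probes above the median signal, the short-minus-long differences of number 1 and of number 2 also correlated, at 0.599. The number split took 46.8% of the sum of squares over these probes, the telomere groups 42.4% and the crossed split 10.8%. The correlations and these shares come from the same 3 contrasts among the 4 arrays, so they restate one structure and are not separate support. Only 3 splits exist, too few for a share under 0.05. Whether the structure by number is a day, a culture or an array position is not in the labels.

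Metallothioneins led the authors' deposited table. One shared signal read by several near-identical probes may account for the 6 names. Of the 14 terms with metallothioneins past the Benjamini threshold, 12 listed no other gene, and the spread between their probes could not be measured without a map from probes to genes, so one signal and several cannot be told apart. A wider oxidative stress response that includes NRF2 targets also stays open, since 1 of 26 was listed (Fisher's exact p = 0.218, odds ratio 4.22, 95% interval 0.102 to 26.1). A change in metal or peroxide handling with telomere length is a biological alternative that was not tested, and the labels carry the same peroxide note for both groups.

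Liver plasma proteins were over-represented among the authors' genes against all protein-coding genes, but the fixed list did not pass against the union of the fixed lists (odds ratio 3.74 against 20.1, adjusted p = 0.131), of whose 963 genes 50 were listed. Counting near-identical genes more than once may account for the call of the acute-phase response term: with ORM1 and ORM2 counted once, its recomputed EASE p was 0.000105 and its enrichment 12.6-fold, but its Benjamini value rose from 0.0127 to 0.163 as 6 genes were left of the 7 in the authors' deposited table. The fixed list holds ORM1 but not ORM2, so counting families once left it at 7 of 45 and could not test this. Easier calling of abundant transcripts stays open. The share listed was 15.6% for hepatocyte secreted proteins and 6.56% for cytosolic ribosomal proteins (Fisher's exact p = 0.198). With 7 of 45 and 4 of 61 genes listed, this comparison had too few genes to decide. It also took both lists as abundant, which was not measured. Abundance and a difference in hepatocyte function between the telomere states cannot be told apart here, because the levels of the genes on the arrays were not known.

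One hypothesis was that genes near chromosome ends are over-represented among the authors' genes, as silencing that spreads from telomeres would predict. Of the 25 outermost protein-coding genes of each chromosome end, 7 were listed where 11.3 were expected, an odds ratio of 0.601 with a 95% interval of 0.238 to 1.27 (Fisher's exact p = 0.218, adjusted p = 0.218 over 3 distances). Among the 10 outermost, 0 of 480 genes were listed where 4.53 were expected (exact p = 0.026, adjusted p = 0.078), and among the 50 outermost 16 were listed where 22.3 were expected (odds ratio 0.69, exact p = 0.174, adjusted p = 0.218). The interval at 25 genes lies below a 2-fold over-representation for the 189 named and matched genes, against all protein-coding genes placed on chromosomes. Which end genes the array measures or the cells express was not known. If fewer are measured, expressed or annotated at the ends than elsewhere, the odds ratio is biased downward, so the interval does not bound a telomere position effect. Both ends of each chromosome were counted by gene order, whatever their distance from the telomere. The authors' input held 229 genes, and those in no annotation cluster, which are not a random part, were not covered. Probes were not tested either, and gene order was taken from the GRCh38.p14 annotation.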
